A study of Pseudotaxus chienii with 9 samples.

How the data were processed

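Leaves of Pseudotaxus chienii were profiled by polyA RNA sequencing in 9 libraries, 3 per group (CK, MeJA for 1 day, MeJA for 2 days), with RNA taken by TRIzol and libraries made with the VAHTS Universal V6 kit, per the labels' protocols. Groups and replicate numbers came from the treatment labels and titles. Reads were trimmed with fastp, aligned with HISAT2 and counted with HTSeq, as far as the names in the submitters' processing notes tell, which give no order or settings. Versions, the genome build, the annotation, the counting settings and the use of strand are not given in the sources used here. The authors deposited 1 table for all libraries, with a column of estimated counts and a column of FPKM per library, a description from sequence matches, KEGG pathways and a position for each gene. The deposited counts were estimated counts rounded up to whole numbers: of 773 low values compared with FPKM, 100% lay 0 to 1 above the value proportional to FPKM (tolerance 0.05, median difference -0.482), and they were used as they stood. The deposited FPKM values are fragments scaled to gene length and library size by the authors' own scaling, whose denominator is not given in the sources used here.

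The table held 26827 genes, 23607 with a description and 3220 without, and 12011 of the descriptions named only an unknown, hypothetical or uncharacterized protein. Gene names in the text are those descriptions, which come from matches to other species and were not tested here. Positions are printed as the table gives them, with a chromosome, a number taken here as the name of a block of that chromosome, and a start and end within it. Reads of near-identical copies, overlapping genes and antisense genes cannot be told apart here. Total counts per library of 48893949 to 58703021 set the counting precision, and a gene at 0 counts in a group was given a floor of 3 counts over the group, which covers counting error only.

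Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, TMM factors of 0.878 to 1.09, filterByExpr with a minimum count of 10) in a single fit of all 9 libraries without covariates, with Benjamini-Hochberg adjustment over the 22384 genes kept and a threshold of 0.05. FPKM served for the levels printed as mean ± SD, and for limma 3.58.1 fits on log2(FPKM + 1) of genes at 1 FPKM or more in at least 3 libraries. The choice of test had been written for either unit, and as counts were present the count test was used. The groups, comparisons, tests, alternatives, 29 gene lists and the rule for named genes were set before the data were examined. Lists were text patterns matched to descriptions. 28 lists were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, and the list for viral, fungal or insect proteins had no members. For each list the mean log2 CPM (counts scaled to library size, prior count 2) of the 6 treated libraries was also compared with that of the 3 CK libraries in a two-sided exact permutation test over 84 splits, whose smallest p is 0.0119. That test, chosen after the files were seen, gave its smallest p for 11 lists, and 14 of 28 lists had an adjusted p under 0.05. The 11 were the lists for jasmonate biosynthesis and turnover, phenylpropanoids, flavonoids, oxidative stress, and ethylene and abscisic acid. They also held AP2/ERF, WRKY and NAC factors, woody tissue, and reproductive and seed tissue. Each had 6 treated libraries above all CK libraries and an adjusted p of 0.0303. Prenyl diphosphate synthases, jasmonate signalling and bHLH factors followed at 0.0476. The permutation test counts the libraries as independent, which the labels do not state. With 3 libraries against 3 there are 10 splits, so no such comparison of a single pair of groups can go below a share of 0.1.

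Genes named in the text were, per comparison, the 5 higher and 5 lower with the largest fold among called genes with a mean of at least 5 FPKM in a group, no overlap between the groups' libraries and an informative description, the members with the lowest adjusted p of each list (4 for the taxane list, 2 for others), and all called taxane genes. A few of these are not printed. The COBRA-like genes, the allergen copies and the genes on lists added later were singled out after their values were seen. Camera directions, medians and means differed in sign at day 1 for heat shock proteins, the MEP pathway, MYB factors and chlorophyll breakdown, at day 2 for heat shock proteins, ribosomal proteins and chlorophyll breakdown, and between the days for the phenylpropanoid, flavonoid, NAC, ethylene and abscisic acid and woody tissue lists. None of these lists was called in the comparison in which its signs differed.

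The fits were tested on simulated data drawn from the means and library sizes of these libraries, with known changes in a seeded set of genes among 22034 kept in the fit. For day 1 against CK, edgeR called 0 of 50 genes changed by 1 on the log2 scale, 18.4% of 49 changed by 2, 47.9% of 48 changed by 3 and 71.7% of 46 changed by 4, with 2 false calls. DESeq2 called 12%, 53.1%, 70.8% and 93.5% with 106 false calls. The alternatives tried were DESeq2 1.42.0, a replicate block, fits of each pair of groups alone, a fold threshold of 1 on the log2 scale, no count filter, each library left out in turn, and limma fits on FPKM with another pseudocount, other filters and other scalings. After the data were seen edgeR with newer dispersion settings, with median-of-ratios factors or with no scaling factors was added, as were fits without both treated libraries numbered 2 and without these and CK library 2. Lists of nuclear photosynthesis genes, plastid-genome names, CYP94 and CYP725A were added at the same stage. Among the 12 CYP94 genes 1 was higher at day 1 and 1 lower at day 2 by edgeR. Adjusted over the list alone, 6 were higher and 1 lower at day 1, and 4 higher and 1 lower at day 2. The median log2 was 2.24 and 2.71 (camera adjusted p = 0.0785 and 0.0193, 0.269 and 0.123 with an estimated correlation). Their score lay above all CK libraries in all 6 treated libraries (two-sided exact permutation p = 0.0119, unadjusted). KEGG pathways with at least 10 tested members were tested with camera as well. No reference genome was used.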

Results

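Messenger RNA was sequenced from leaves of Pseudotaxus chienii, a conifer of the yew family, in 9 libraries. The labels put 3 libraries in each of 3 groups. CK is the group whose label names no methyl jasmonate, and the other groups carry the label of methyl jasmonate (MeJA, a volatile hormone of the wound and defence response of plants) for 1 day or for 2 days. The series title names taxane biosynthesis, the pathway to paclitaxel in yews, so the comparisons asked which genes of that pathway and of the hormone response differed between treated and CK leaves. The labels do not say whether CK leaves had a mock treatment or when they were sampled, so a difference from CK may also hold effects of handling or time. Total estimated counts ran from 48893949 in day 2 library 1 to 58703021 in day 2 library 3, and 23194 to 24252 of the 26827 genes had a count above 0. The labels do not say that the libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

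Treated libraries lay apart from CK libraries, and the treated groups were less uniform than CK. On the first principal component of log2 CPM (counts scaled to library size), which held 42.8% of the variance, the CK libraries lay between -171 and -107 and the treated ones between 29.7 and 131. The second component held 24.2% and set day 1 library 2 at 207, with the other 8 libraries between -82.9 and 27.0. Across genes, which are not independent replicates, the CK libraries correlated with each other at 0.936 to 0.945 (Pearson). Day 1 library 2 correlated with the other day 1 libraries at 0.829 and 0.818. Day 1 libraries 1 and 3 correlated with each other at 0.930, less than with the day 2 library of the same number (0.958 and 0.959). No pair of libraries of a group matched within sampling noise, since the chi-square per degree of freedom of their counts ran from 103 to 989.

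After 1 day of MeJA, genes named for taxane biosynthesis had higher estimates than in CK, with a wide spread between libraries, and 2 of the 55 tested (62 in the table) passed the test. 10-Deacetylbaccatin III 10-O-acetyltransferase (DBAT), which makes baccatin III, the core of paclitaxel, rose from 0.384 ± 0.00911 FPKM in CK to 18.8 ± 14.3 (SD, n = 3 in each group). This gene is PchiChr11G300670 on chromosome 11, block 1, 97823384 to 97824981, and its log2 fold change was 5.78 (SE 0.89, edgeR adjusted p = 0.0140). A 3'-N-debenzoyltaxol N-benzoyltransferase (PchiChr4G123700, chromosome 4, block 1000000001, 380260329 to 380262044), named for the step that adds the benzoyl group of the paclitaxel side chain, rose from 9.10 ± 1.65 to 54.5 ± 37.3 FPKM (log2 2.76, SE 0.61, edgeR adjusted p = 0.0424). None of the 6 other tested genes with this name or its 2'-deoxytaxol form passed at either day. A taxadienol acetyltransferase (PchiChr9G253100, chromosome 9, block 1, 145986522 to 145991178) was at 1.84 ± 2.35 FPKM in CK and at 72.8 ± 63.3 after 1 day, which did not pass (edgeR adjusted p = 0.0773).

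In the whole taxane list 54 of the 55 tested genes had a positive estimate, with a median log2 fold change of 4.72 (26.3-fold), and 1 gene passed when adjusted over the list alone. With each library left out in turn the median ran from 3.22 (without day 1 library 3) to 11.5 (without CK library 2). Without CK library 2 the CK level rests on libraries 1 and 3, where at least 13 members were under 0.1 CPM. The size of 11.5 is therefore uncertain, and the 26.3-fold of the full fit depends on CK library 2. The set test (camera, preset correlation of 0.01) gave an adjusted p of 1.27e-08, and adjusted p = 0.555 with an estimated correlation. The mean log2 CPM of the list were -3.63, 1.93 and -3.67 in CK libraries 1, 2 and 3 and 4.39, -1.37 and 6.06 in day 1 libraries 1, 2 and 3, so day 1 library 2 lay below CK library 2. Over the 6 treated against the 3 CK libraries, a two-sided exact permutation test of this score gave p = 0.0357 and 0.0667 after adjustment over the 28 lists, and 5 of 6 treated libraries lay above all CK libraries. Many members carry the same name and sit beside each other, so reads of near-identical copies could have been split between them and their single values are uncertain. The CYP725A family, the cytochromes P450 that hold the known taxane hydroxylases, was added as a list after the values were seen: 11 of its 33 tested genes rose at day 1 and 21 when adjusted over the list alone (median log2 4.56, camera adjusted p = 3.76e-13, adjusted p = 0.118 with an estimated correlation).

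**Figure D1:**
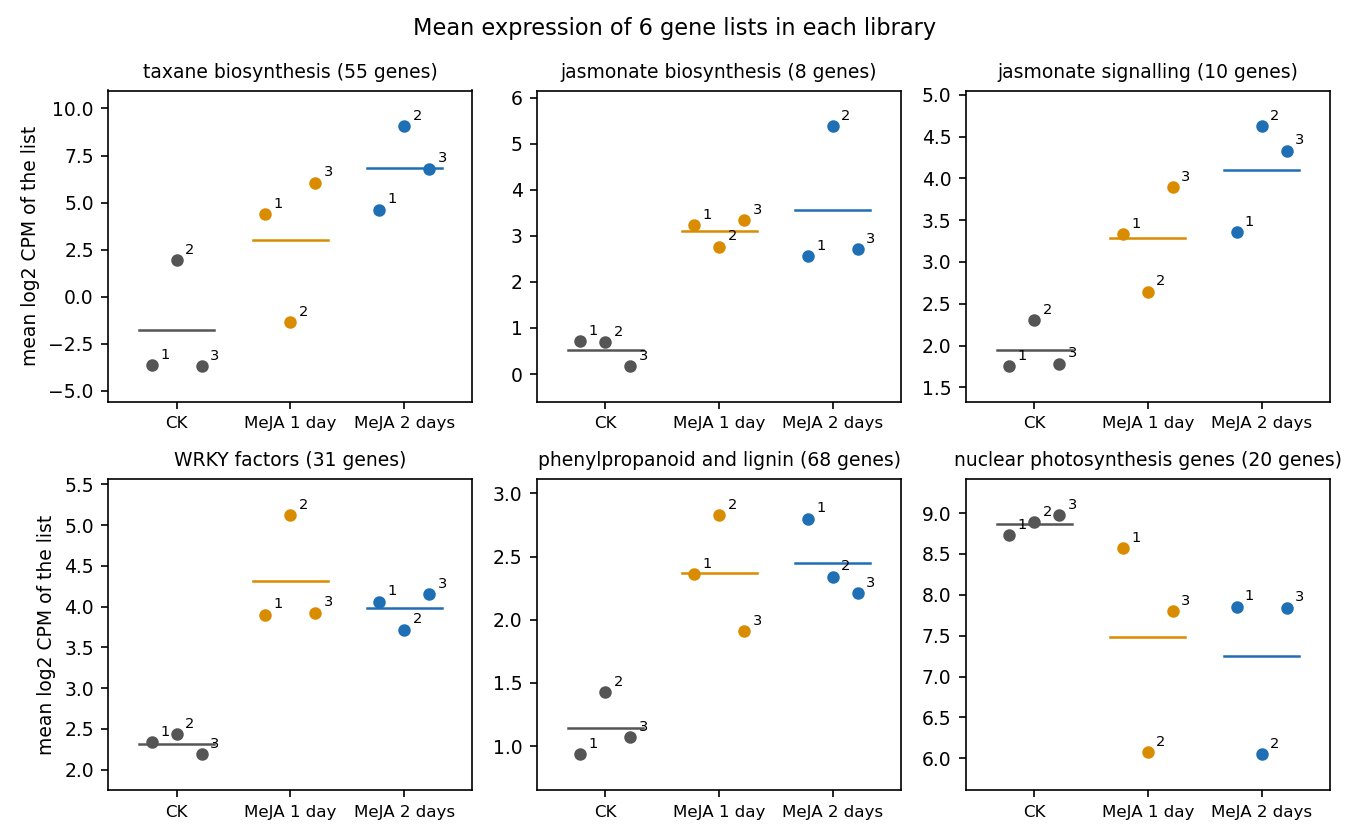
Mean log2 CPM of 6 gene lists in each library, by group on the horizontal axis. Points are libraries with their replicate number, horizontal lines are group means, the vertical scales differ between panels, and the nuclear photosynthesis list was chosen after the values were seen. In the taxane panel CK library 2 (1.93) lay above day 1 library 2 (-1.37), and in the WRKY panel all 6 treated libraries lay above the CK libraries.

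Genes that supply the precursors of taxanes mostly did not pass at day 1. In the mevalonate pathway 1 of 5 tested genes rose, a 3-hydroxy-3-methylglutaryl-CoA reductase that catalyses its committed step (PchiChr10G292440, 11.4 ± 1.26 to 44.8 ± 22.8 FPKM, edgeR adjusted p = 0.0449), and 4 passed when adjusted over the list alone. Leaving out any of the 9 libraries ended the call of PchiChr10G292440, with edgeR adjusted p values of 0.0516 to 0.159. None of 12 genes of the plastid MEP pathway, 9 prenyl diphosphate synthases and 18 other terpene synthases passed over all genes. Adjusted over the list alone, 3 prenyl diphosphate synthases were higher and 1 lower, and 0 genes of the MEP pathway and of the other terpene synthases passed. The camera adjusted p values of these 4 lists ran from 0.0803 for the mevalonate pathway to 0.810 for the MEP pathway.

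Genes of the hormone's own signalling were among those that rose. MYC2a, the transcription factor that switches on jasmonate-responsive genes (PchiChr2G047860, chromosome 2, block 1, 445536507 to 445539843), went from 7.45 ± 2.36 to 34.7 ± 5.33 FPKM (SD, n = 3), a log2 fold change of 2.37 (SE 0.28, edgeR adjusted p = 0.00718). TIFY 9, a member of the family of JAZ repressors (PchiChr3G086840), went from 6.27 ± 3.90 to 338 ± 341 FPKM (edgeR adjusted p = 0.0283). These were the 2 of 10 jasmonate signalling genes called, and 5 passed when adjusted over the list alone. In jasmonate biosynthesis 2 of 8 rose, and 2 when adjusted over the list alone. They were lipoxygenase 1, which oxygenates linolenic acid (PchiChr2G052390, 0.325 ± 0.243 to 85.4 ± 121 FPKM, edgeR adjusted p = 0.0282), and 12-oxophytodienoate reductase 7 (PchiChr7G216060). The latter had 0 counts in CK and was at least 157-fold higher at day 1, against a floor of 3 counts over the group (edgeR adjusted p = 0.0328). Its log2 fold change ran from 1.18 to 10.8 over the alternative fits, so its size is uncertain. The list's median log2 was 4.91, or 3.42 with the genes at 0 in a group set to their bound (camera adjusted p = 0.0803, 0.555 with an estimated correlation), and it was 0.69 without day 1 library 3. Of 30 genes of jasmonate turnover 1 rose, CYP94P7 (PchiChr9G254860, edgeR adjusted p = 0.0448), of a P450 family with members that oxidise the hormone. Adjusted over the list alone 4 passed. That list's pattern also took in CYP947 genes, and among the 12 CYP94 genes proper, a list added later, the same gene was the 1 called.

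Some transcription factors rose as well. Of 31 WRKY genes, regulators of defence, 13 rose and none fell by edgeR over all genes, and 20 were higher and 1 lower when adjusted over the list alone. The median log2 was 2.16, and camera gave an adjusted p of 5.25e-10 and adjusted p = 0.273 with an estimated correlation. PchiChr9G253780 rose from 3.37 ± 0.798 to 17.0 ± 2.70 FPKM (edgeR adjusted p = 0.00705) and PchiChr10G284800 from 6.45 ± 4.13 to 115 ± 36.2 (edgeR adjusted p = 0.00953). Among 42 AP2/ERF factors, which act in ethylene and stress responses, 9 rose (15 higher and 1 lower when adjusted over the list alone), with a median log2 of 1.10 (camera adjusted p = 0.00988, 0.273 with an estimated correlation). A TINY-type member (PchiChr12G324200) went from 1.02 ± 0.719 to 29.7 ± 21.0 FPKM (edgeR adjusted p = 0.0136). Called genes numbered 4 of 26 in bHLH, 2 of 24 in NAC and 1 of 20 in MYB factors, none of these lists was called (camera adjusted p = 0.236, 0.0803 and 0.817), and 7, 3 and 1 genes passed when adjusted over the list alone. MYB12 (PchiChr3G071180), named for a regulator of flavonol synthesis, rose from 1.27 ± 0.581 to 23.4 ± 11.9 FPKM (edgeR adjusted p = 0.0106). bHLH041 (PchiChr2G064150) rose from 1.28 ± 0.264 to 13.0 ± 3.91 FPKM (edgeR adjusted p = 0.00461).

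Some enzymes of phenolic and oxidative defence also rose at day 1. A flavonol synthase or flavanone 3-hydroxylase (PchiChr11G311480, chromosome 11, block 500000001, 317118923 to 317120628), of the route to flavonols, went from 1.21 ± 0.437 to 21.6 ± 2.52 FPKM (log2 4.30, SE 0.31, edgeR adjusted p = 0.00253), and leucoanthocyanidin reductase, of the branch to catechins, fell from 4.92 ± 3.79 to 0.465 ± 0.152 (PchiChr6G169620, edgeR adjusted p = 0.0324). They were the 2 called of 18 flavonoid genes, of which 5 were higher and 1 lower when adjusted over the list alone. A dirigent protein, of the family that guides lignan formation (PchiChr2G041200), went from 48.1 ± 17.6 to 428 ± 122 FPKM (edgeR adjusted p = 0.00705). In the phenylpropanoid and lignin list 5 of 68 genes rose and 2 fell (16 and 2 when adjusted over the list alone), with camera adjusted p = 0.00865 and adjusted p = 0.387 with an estimated correlation. Of 107 genes of glutathione and oxidative stress 11 rose (15 higher and 1 lower over the list alone, camera adjusted p = 0.0654), among them peroxidases, which use hydrogen peroxide in wall and defence chemistry. PchiChr8G221830 went from 1.78 ± 0.277 to 15.7 ± 4.23 FPKM and PchiChr5G147320 from 3.79 ± 0.773 to 54.0 ± 18.6 (edgeR adjusted p = 0.00363 for both). Of 64 defence proteins 2 rose, both named chitinases, enzymes that cut fungal cell walls (PchiChr6G178690, 16.4 ± 3.41 to 89.7 ± 26.6 FPKM, and PchiChr4G105200), and 1 passed over the list alone (camera adjusted p = 0.639).

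Among the other lists the ethylene and abscisic acid genes had 17 of 17 positive estimates (median log2 1.60, camera adjusted p = 0.00865, 0.387 with an estimated correlation). One of them rose, an ACC oxidase that makes ethylene (PchiChr8G225290, log2 6.79, SE 1.58, edgeR adjusted p = 0.0477), and 2 passed when adjusted over the list alone. PchiChr8G225290 was at 58.2, 2205 and 76.9 FPKM in day 1 libraries 1, 2 and 3, against 6.83 to 9.95 in CK, and its log2 fold change was 3.10 without day 1 library 2. It lost the call in 16 of 25 settings. The median was 0.59 without day 1 library 2. The list for woody tissue and secondary wall had a median log2 of 1.94 (camera adjusted p = 0.00988, 0.387 with an estimated correlation) and 2 of 23 called genes, both COBRA-like, of a family that acts in cellulose deposition, with 9 higher and 1 lower over the list alone. Its median was 0.92 without day 1 library 3, and the list was not called without CK library 1 or day 1 library 1 (camera adjusted p = 0.104 and 0.0834). The list for reproductive and seed tissue had 12 of 52 genes higher and 14 over the list alone (median log2 0.74, camera adjusted p = 0.0110, 0.482 with an estimated correlation). Of those 12, 11 were neighbouring copies named for 1 pollen major allergen, whose reads could have been split between them, so they are uncertain as single genes. In the cell cycle and histone list 1 of 41 genes rose, a histone H3 (PchiChr2G058100), and 1 fell, a histone H2B (PchiChr2G059440). A ribosomal protein L10 (PchiChr10G292250) was the 1 called of 60 cytosolic ribosomal proteins and 1 of 37 epidermis, wax and cutin genes rose. No gene passed by edgeR in the lists for guard cells (6 tested), chlorophyll breakdown (6) and organelle-encoded transcripts (16), and camera called none of the last 6 lists named (adjusted p = 0.0803 to 0.829).

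Genes that fell at day 1 were fewer. FTSH2, a protease that turns over photosystem II proteins in the chloroplast (PchiChr10G282200, chromosome 10, block 1, 201055254 to 201059596), fell from 90.9 ± 37.9 to 6.61 ± 5.14 FPKM (log2 -3.68, SE 0.73, edgeR adjusted p = 0.0305). Small heat shock proteins PchiChr8G227500 (103 ± 43.8 to 13.1 ± 3.96 FPKM, edgeR adjusted p = 0.0125) and PchiChr7G193160 (55.4 ± 17.8 to 7.37 ± 3.04, edgeR adjusted p = 0.0109), which bind unfolded proteins, fell too. So did a mitochondrial heat shock protein of 70 kDa (PchiChr6G166600, log2 -0.97, edgeR adjusted p = 0.0110) and a heat shock cognate protein of 70 kDa (PchiChr11G317100, 476 ± 25.5 to 129 ± 20.8 FPKM, edgeR adjusted p = 0.0378). The day 1 call of PchiChr11G317100 was not followed with libraries left out. Of the 88 tested genes in the list of heat shock proteins and chaperones 3 fell, and 3 over the list alone, and PchiChr8G227500 is not on it because its description is spelled with a hyphen. That list had a median log2 of -0.11 but a mean of 0.10, and camera gave an adjusted p of 0.0567 in the lower direction. A CASP-like membrane protein (PchiChr1G028440, 9.54 ± 2.26 to 0.505 ± 0.459 FPKM) and an AP2/B3-like factor (PchiChr12G329690, 10.8 ± 0.978 to 1.49 ± 0.723) fell as well. Among genes that rose was one described as a subunit of chromatin assembly factor 1, which deposits histones on DNA (PchiChr6G170800, chromosome 6, block 1, 246287691 to 246288290). It was at 0 counts in CK and 7.12 ± 1.36 FPKM at day 1, at least 266-fold higher against the floor (edgeR adjusted p = 0.00708). Its log2 fold change ran from 2.88 to 11.2 over the alternative fits, so its size is uncertain.

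Genes named for nuclear photosynthesis proteins and genes with plastid-genome names had medians of opposite sign. The fixed list had 115 tested genes, none called over all genes or over the list alone, and a median log2 of 1.43 at day 1 (camera adjusted p = 0.0118, 0.844 with an estimated correlation). The call ended without CK library 1 or day 1 library 1 or 2 (0.174, 0.608 and 0.307). Most of its members carried names of plastid-encoded proteins, and the list's direction turned in limma fits on FPKM, to a median log2 of -0.87 with a pseudocount of 0.1, -0.68 with median-of-ratios scaling and -1.66 with a mean of at least 5 FPKM. It was also negative with a pseudocount of 1 (-0.81) and after quantile normalisation (-0.83). Those fits kept only 35 of its genes, or 20 with the mean of 5 FPKM, so the set of genes changed along with the method. After this was seen, 20 nuclear photosynthesis genes were tested alone. Their median log2 was -1.18 at day 1 and -1.60 at day 2, with 18 of 20 estimates negative at both days (camera adjusted p = 3.98e-04 and 2.52e-05, 0.417 and 0.344 with an estimated correlation). Their mean log2 CPM were 8.73 to 8.98 in CK, 6.08 in day 1 library 2, 6.05 in day 2 library 2 and 7.80 to 8.57 in the other treated libraries (two-sided exact permutation p = 0.0476). Descriptions of 967 genes in the table matched names of plastid-genome proteins, which does not show that the transcripts came from the plastid. The 397 tested had a median log2 of 1.70 at day 1 and 0.92 at day 2 (0.417 and 0.575 as camera adjusted p with an estimated correlation). They averaged a low -1.71 log2 CPM in CK. Their score did not part treated from CK libraries (two-sided exact permutation p = 0.155), with day 1 library 3 at -2.24 and day 2 library 3 at -1.15 inside the CK range of -2.40 to -0.88.

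In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1196 of 22384 genes at day 1 against CK, 972 higher and 224 lower, and 1144 of these changed at least 2-fold. The unadjusted p was under 0.05 for 5328 genes, where chance gives 1119.2, and 689 called genes had no informative description. The count was 134, 356 and 142 without CK library 1, 2 or 3, 796 without day 1 library 3, 689 and 594 without day 2 library 1 or 3, and 1803 (1349 higher) without both treated libraries numbered 2. It was 534 in a fit of these groups alone and 3742 by DESeq2 (2440 higher, 1302 lower). Quantile normalisation of FPKM gave 891 higher and 899 lower. Of the 39 named genes called at day 1, 27, 19 and 29 lost the call without CK library 1, 2 or 3, 6, 7 and 8 without day 1 library 1, 2 or 3, and 13, 8 and 17 without day 2 library 1, 2 or 3. DBAT (PchiChr11G300670) lost it without any CK library (edgeR adjusted p up to 0.0775). The debenzoyltaxol benzoyltransferase PchiChr4G123700 lost it without 7 of the 9 libraries (up to 0.147, without CK library 3) and MYC2a (PchiChr2G047860) without CK library 1 (0.0524). The call held for 9 genes in every setting that tested them (24 for PchiChr6G170800 and 25 for the others). These were PchiChr11G311480, PchiChr8G221830, PchiChr5G147320, PchiChr2G064150, PchiChr2G041200, PchiChr6G178690, PchiChr9G253780, PchiChr6G170800 and a bHLH112-like factor, PchiChr2G037800 (1.83 ± 0.213 to 7.69 ± 1.02 FPKM). The number of lists called by camera at the preset correlation was 8 of 28, all higher, none with an estimated correlation (smallest adjusted p = 0.273), and 5 in a fit of these groups alone.

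Other genes given here by ID lost the day 1 call when 1 library was left out. The histone H2B PchiChr2G059440 lost it without any of the 9 libraries (edgeR adjusted p = 0.0580 to 0.165). PchiChr1G028440 and PchiChr9G254860 lost it without 8 libraries (highest edgeR adjusted p = 0.130 and 0.152), PchiChr10G292250 and PchiChr6G169620 without 7 (0.166 and 0.102). PchiChr10G282200, PchiChr4G105200 and PchiChr8G225290 lost it without 6 (0.0891, 0.161 and 0.165), PchiChr7G216060 without 5 (0.103), and PchiChr2G052390 and PchiChr3G086840 without 4 (0.116 for both). PchiChr2G058100 lost it without 3 (0.0757), and PchiChr10G284800, PchiChr12G324200, PchiChr12G329690, PchiChr3G071180 and PchiChr6G166600 without 2 (0.0557 to 0.0772). PchiChr7G193160 and PchiChr8G227500 lost it without CK library 3 (0.0550 and 0.0545).

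After 2 days of MeJA 3 of the 55 tested taxane genes passed against CK. DBAT (PchiChr11G300670) was at 20.9 ± 15.2 FPKM against 0.384 ± 0.00911 in CK (SD, n = 3, log2 5.92, SE 0.89, edgeR adjusted p = 0.0144) and the debenzoyltaxol benzoyltransferase PchiChr4G123700 at 57.2 ± 28.5 against 9.10 ± 1.65 (log2 2.82, SE 0.62, edgeR adjusted p = 0.0419). The taxadienol acetyltransferase PchiChr9G253100, which acts early in the pathway, rose to 353 ± 366 FPKM from 1.84 ± 2.35 (log2 7.78, SE 1.65, edgeR adjusted p = 0.0386). The median log2 of the list was 7.41 (170-fold), with 54 of 55 estimates positive, and 37 genes passed when adjusted over the list alone. With each library left out in turn the median ran from 5.85 (without day 2 library 2) to 15.5 (without CK library 2). In CK libraries 1 and 3 at least 13 members were under 0.1 CPM, so the size of 15.5 is uncertain. The 170-fold of the full fit depends on CK library 2. Camera gave an adjusted p of 1.66e-19, and adjusted p = 0.356 with an estimated correlation. The list's mean log2 CPM in day 2 libraries 1, 2 and 3 were 4.62, 9.05 and 6.80, against 1.93 in the highest CK library and 4.39, -1.37 and 6.06 at day 1. In the CYP725A family, the list added later, 13 of 33 genes rose (30 over the list alone, adjusted p = 0.0651 with an estimated correlation). CYP725A13 (PchiChr9G256610, chromosome 9, block 1, 232735294 to 232737485), at 0 counts in CK, was at least 638-fold higher against the floor of 3 counts (edgeR adjusted p = 0.0369). Its log2 fold change ran from 2.02 to 12.9 over the alternative fits, so its size is uncertain, and it lost the call in 13 of 24 settings.

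**Figure D2:**
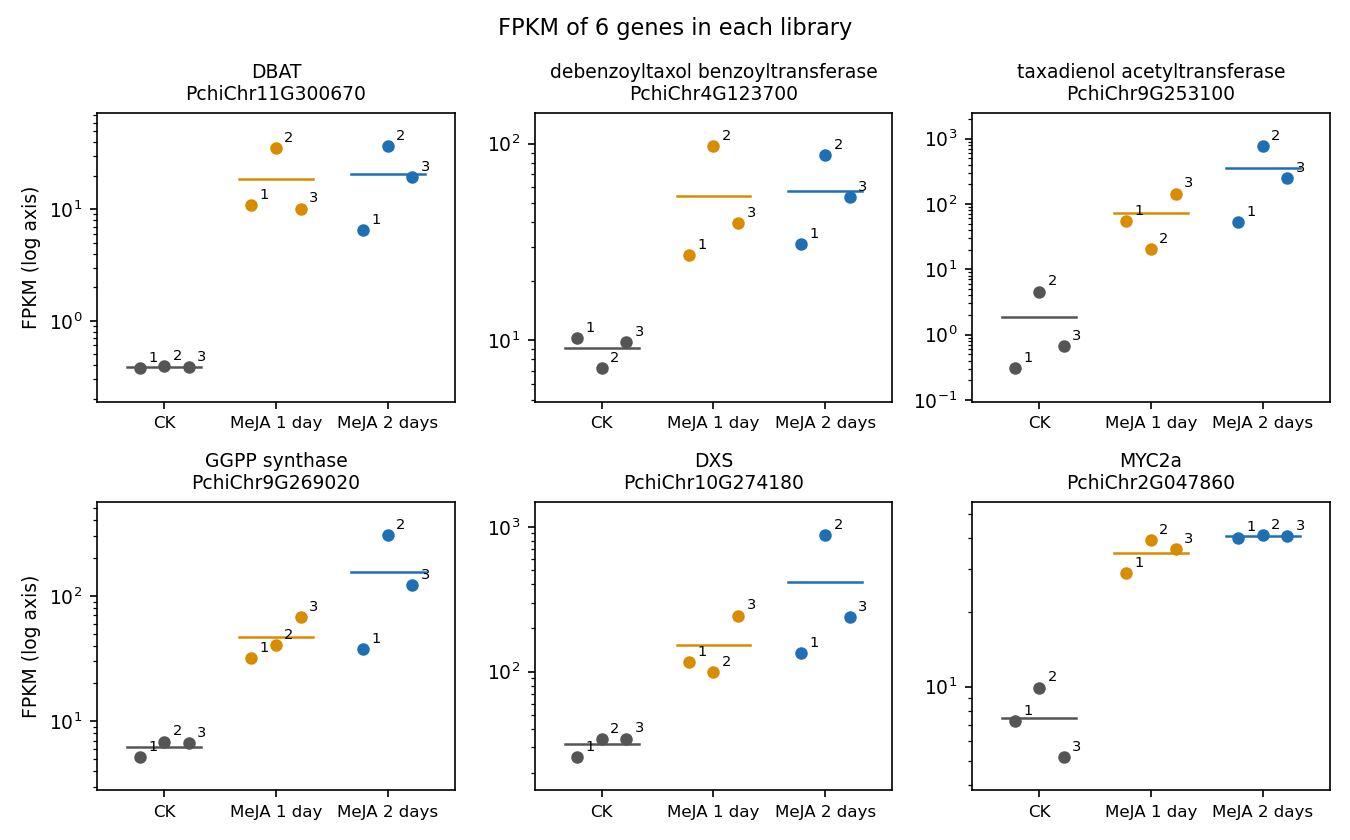
FPKM of 6 genes in each library on log axes, by group. Points are libraries with their replicate number, horizontal lines are group means and the vertical scales differ between panels. DBAT lay at 0.374 to 0.392 FPKM in CK and at 6.46 to 36.8 in the treated libraries.

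Of the genes that supply the diterpenoid precursor a few rose at day 2. Of 9 prenyl diphosphate synthases 2 rose, both geranylgeranyl diphosphate synthases, which make the substrate of the first step to taxanes. PchiChr9G269020 (chromosome 9, block 999758136, 85325052 to 85327157) went from 6.25 ± 0.916 FPKM in CK to 156 ± 138 and PchiChr9G269010, its neighbour of the same name, from 6.62 ± 3.02 to 205 ± 197 (edgeR adjusted p = 0.0189 and 0.0245). As reads can be split between such copies, their single values are uncertain. In the MEP pathway 1 of 12 genes rose, 1-deoxy-D-xylulose 5-phosphate synthase, its entry enzyme (PchiChr10G274180, chromosome 10, block 1, 2579829 to 2586146), from 31.5 ± 4.92 to 417 ± 405 FPKM (log2 3.93, SE 0.80, edgeR adjusted p = 0.0347). Adjusted over the list alone, 4 prenyl diphosphate synthases were higher and 1 lower, 3 MEP genes and 1 mevalonate gene were higher and none of the 18 other terpene synthases passed, and camera called none of these 4 lists (adjusted p = 0.0756, 0.641, 0.215 and 0.410). None of 5 mevalonate genes and 18 other terpene synthases passed by edgeR over all genes.

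MYC2a (PchiChr2G047860) stood at 40.6 ± 0.537 FPKM at day 2 (log2 2.57, SE 0.28, edgeR adjusted p = 0.00758), and a JAZ repressor (PchiChr12G333780) rose from 57.2 ± 2.00 to 136 ± 24.7 (edgeR adjusted p = 0.0277). They were among 3 of 10 jasmonate signalling genes that rose (5 over the list alone, camera adjusted p = 0.0831). In jasmonate biosynthesis 1 of 8 rose, PchiChr7G216060, at least 80.7-fold higher (edgeR adjusted p = 0.0419, log2 0.73 to 9.78 over the alternative fits). Over the list alone 3 passed, and the list was higher (median log2 5.40, camera adjusted p = 0.0449, 0.377 with an estimated correlation). It was not called without CK library 1, 2 or 3, day 1 library 1 or 3 or day 2 library 2 (0.0693 to 0.141). CYP94D82 (PchiChr7G203650), of a P450 family with members that oxidise jasmonates, fell from 87.3 ± 3.63 to 33.2 ± 9.50 FPKM (edgeR adjusted p = 0.0412). It was the 1 called of 30 turnover genes, also over the list alone. The 12 CYP94 genes proper, a list added later, had a median log2 of 2.71 at day 2. Over that list alone 4 were higher and 1 lower (camera adjusted p = 0.0193, 0.123 with an estimated correlation). Of 31 WRKY factors 9 rose (17 higher and 1 lower over the list alone, median log2 1.65, camera adjusted p = 5.49e-07, 0.260 with an estimated correlation). PchiChr10G284800 stood at 141 ± 46.0 FPKM (edgeR adjusted p = 0.00961). Of 42 AP2/ERF factors 6 rose (9 higher and 1 lower over the list alone, camera adjusted p = 0.0484, 0.260 with an estimated correlation) and of 24 NAC factors 1 rose and 3 over the list alone (camera adjusted p = 0.0421, 0.260 with an estimated correlation). The AP2/ERF list was not called without CK library 1, day 1 library 1 or day 2 library 3 (0.0907, 0.0532 and 0.0832). The NAC list was not called without CK library 2 or 3, day 1 library 1 or 3 or day 2 library 2 or 3 (0.0515 to 0.0832). In the bHLH and MYB lists 5 of 26 and 1 of 20 genes rose (8 and 1 over the list alone, camera adjusted p = 0.0617 and 0.512).

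The phenolic and oxidative enzymes of day 1 stood at similar levels at day 2. The flavonol synthase PchiChr11G311480 was at 21.0 ± 1.58 FPKM against 1.21 ± 0.437 in CK (log2 4.23, SE 0.31, edgeR adjusted p = 0.00370), the dirigent protein PchiChr2G041200 at 438 ± 59.1 against 48.1 ± 17.6 (edgeR adjusted p = 0.00912) and the peroxidase PchiChr8G221830 at 15.7 ± 2.60 against 1.78 ± 0.277 (edgeR adjusted p = 0.00370). Of 68 phenylpropanoid and lignin genes 5 rose and 1 fell (20 and 1 over the list alone, camera adjusted p = 0.00175, 0.260 with an estimated correlation). In the flavonoid list 1 of 18 rose and 1 fell, the same genes as at day 1 (4 and 2 over the list alone), and 11 of 107 genes of glutathione and oxidative stress rose (14 over the list alone, camera adjusted p = 0.112). Chitinases PchiChr6G178690 and PchiChr4G104580 were the 2 of 64 defence genes that rose (1 over the list alone). The ethylene and abscisic acid list was higher (median log2 1.58, camera adjusted p = 0.00150, 0.260 with an estimated correlation) with 0 of 17 genes called by edgeR over all genes and 8 over the list alone. Woody tissue and secondary wall had 3 of 23 genes higher (8 higher and 1 lower over the list alone, camera adjusted p = 0.00310, 0.260 with an estimated correlation), and reproductive and seed tissue 11 higher and 1 lower of 52 (camera adjusted p = 0.0850), again led by the allergen copies.

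Large changes at day 2 outside these groups included jacalin-related lectin 3 (PchiChr1G000340), a sugar-binding protein, from 0.0289 ± 0.0317 to 56.4 ± 89.5 FPKM (edgeR adjusted p = 0.0480). Another was a LOB-domain transcription factor (PchiChr12G328590) at 0 counts in CK and at least 262-fold higher against the floor (edgeR adjusted p = 0.0277). The log2 fold change of PchiChr12G328590 ran from 2.28 to 11.6 over the alternative fits, so its size is uncertain, and it lost the call in 12 of 24 settings. FTSH2 (PchiChr10G282200) again fell, to 6.75 ± 3.02 FPKM from 90.9 ± 37.9 (edgeR adjusted p = 0.0313). A dormancy or auxin associated protein (PchiChr3G076750, chromosome 3, block 1, 366177601 to 366179615) fell from 608 ± 210 FPKM in CK by a log2 fold change of -2.85 (SE 0.61, edgeR adjusted p = 0.0392) and the ubiquitin ligase MIEL1 (PchiChr4G102480) from 11.8 ± 3.05 to 1.74 ± 0.836 (edgeR adjusted p = 0.0144). CYP750C17 (PchiChr1G001020), a cytochrome P450, fell from 38.5 ± 17.2 to 2.80 ± 1.54 FPKM (edgeR adjusted p = 0.0337). The 1 called photosynthesis gene, a ferredoxin-NADP reductase of the type the table names for embryos (PchiChr9G264020), rose from 33.5 ± 4.99 to 160 ± 77.3 FPKM (edgeR adjusted p = 0.0304). The photosynthesis list was not called at day 2 (median log2 0.61, camera adjusted p = 0.498) and had a median of -2.08 over the 20 genes left where a mean of at least 5 FPKM was required. Of 88 heat shock proteins and chaperones none passed by edgeR, with a median log2 of 0.07 and a camera direction of lower (adjusted p = 0.814).

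**Figure D3:**
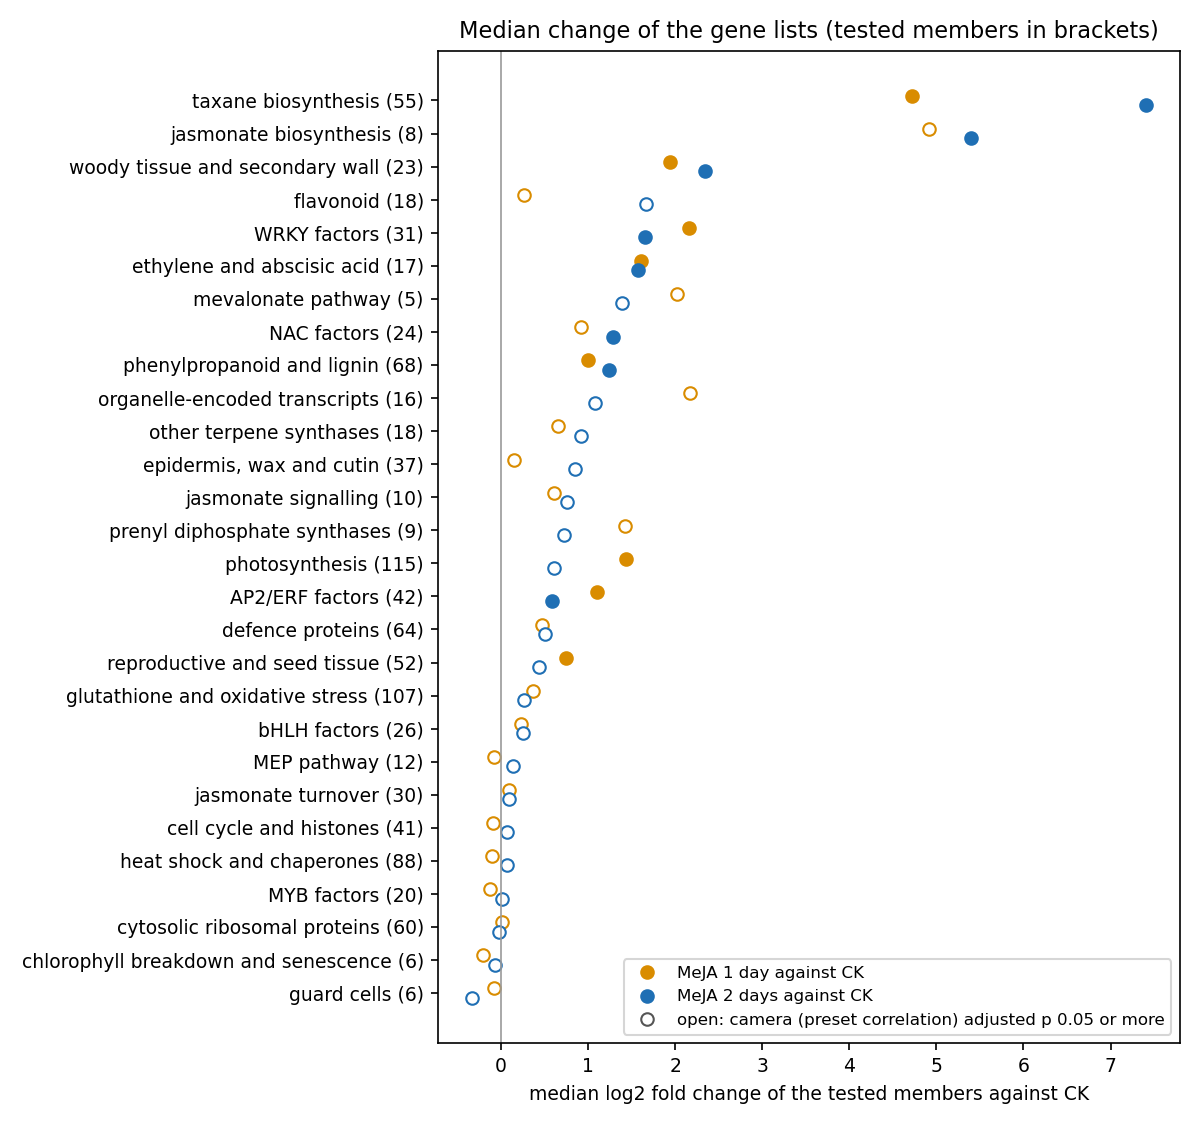
Median log2 fold change against CK of the tested members of each of the 28 lists, at day 1 (orange) and day 2 (blue), with the number tested in brackets. Filled points passed camera at the preset correlation after adjustment, 8 lists at each day, and no list passed with an estimated correlation. The photosynthesis median at day 1 was negative in 5 limma fits on FPKM, which kept fewer of its genes.

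At day 2 against CK edgeR called 1107 genes, 915 higher and 192 lower, of which 1050 changed at least 2-fold, with 5526 genes at an unadjusted p under 0.05 and 628 called genes without an informative description. Without CK library 1, 2 or 3 the count was 48, 372 and 204, without day 1 library 2 it was 2893, and without day 2 library 1, 2 or 3 it was 665, 432 and 499. It was 2430 (1587 higher) without both treated libraries numbered 2, 1945 in a fit of these groups alone, 4012 by DESeq2 (2610 higher, 1402 lower) and 2622 after quantile normalisation of FPKM (1125 higher, 1497 lower). Of the 38 named genes called, 34, 25 and 29 lost the call without CK library 1, 2 or 3, 11, 0 and 12 without day 1 library 1, 2 or 3, and 10, 20 and 20 without day 2 library 1, 2 or 3. The call of DBAT (PchiChr11G300670) ended without any CK library, with an edgeR adjusted p of up to 0.0775, that of PchiChr4G123700 without 6 of the 9 libraries (up to 0.149, without CK library 3) and that of the taxadienol acetyltransferase PchiChr9G253100 without 7 (up to 0.152, without CK library 3). PchiChr11G311480, PchiChr8G221830, PchiChr5G147320 and PchiChr2G064150 kept the call in all 25 settings. Camera called 8 of 28 lists at the preset correlation (5 without day 1 library 1), and none with an estimated correlation (smallest adjusted p = 0.260).

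Other genes given here by ID lost the day 2 call when 1 library was left out. PchiChr1G000340 and PchiChr6G169620 lost the call without 8 libraries (highest edgeR adjusted p = 0.174 and 0.128). PchiChr10G282200, PchiChr1G001020, PchiChr3G076750, PchiChr4G104580, PchiChr7G203650 and PchiChr7G216060 lost it without 7 (0.102 to 0.139), and PchiChr9G256610 without 6 (0.116). PchiChr10G274180, PchiChr12G328590, PchiChr12G333780 and PchiChr9G264020 lost it without 5 (0.0902 to 0.138), PchiChr6G178690, PchiChr9G269010 and PchiChr9G269020 without 3 (0.0853 to 0.119) and PchiChr4G102480 without 2 (0.0583). PchiChr10G284800, PchiChr2G041200, PchiChr2G047860 and PchiChr3G071180 lost it without CK library 1 (0.0504 to 0.0605).

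Many genes were called at both days, among them DBAT, the debenzoyltaxol benzoyltransferase PchiChr4G123700, MYC2a, the flavonol synthase and the dirigent protein. In all 789 genes were called in the same direction in both comparisons, 690 higher and 99 lower. Independent lists of these sizes would share 39.7 higher and 1.92 lower genes. In 20 draws all libraries, CK included, were simulated from the CK means with no effect, and 0 genes were shared. With no effect hardly any gene can be called, so this 0 does not measure how far shared controls raise an overlap. The fold changes correlated at 0.857 across genes against 0.496 in the simulation, and their covariance was 2.51 against 0.361. As both comparisons use the same 3 CK libraries, which could not be split into parts of at least 2, some of the excess may come from these controls. A further 282 genes were called higher and 125 lower at day 1 alone, and 225 higher and 93 lower at day 2 alone, which does not show a difference between the days. The shared count was 42 to 275 without CK library 1, 2 or 3 (42 without library 1 and 275 without library 2), 465 without day 1 library 3 and 411, 396 and 361 without day 2 library 1, 2 or 3. It was 440 with each pair of groups fitted alone, 2511 by DESeq2, 1417 after quantile normalisation and 1442 without both treated libraries numbered 2.

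Between day 2 and day 1 no single gene passed by edgeR, and a few gene lists differed at the preset correlation. All 55 taxane genes had a higher estimate at day 2 (median log2 2.55, camera adjusted p = 1.72e-15, 0.670 with an estimated correlation). With each library left out in turn this median ran from 1.16 (without day 2 library 2) to 4.34 (without day 1 library 3). A gene described as a baccatin 2-O-benzoyltransferase (PchiChr5G143700), which benzoylates the taxane ring, was at 12.1 ± 17.6 FPKM at day 1 and 401 ± 641 at day 2 (log2 5.25, SE 2.57, edgeR adjusted p = 0.954). WRKY factors stood lower at day 2, with 25 of 31 estimates negative (median log2 -0.42, camera adjusted p = 0.0227, 0.670 with an estimated correlation), but without day 1 library 2 the median was 0.02 (camera adjusted p = 0.772), and without day 2 library 2 or 3 the list was not called (0.178 and 0.0586). The photosynthesis list, most of it genes with plastid-genome names, was lower in 111 of 115 estimates (median log2 -0.73, camera adjusted p = 0.00157, 0.728 with an estimated correlation). That median ran from -1.20 (without day 1 library 3) to -0.33 (without day 1 library 1), and the call ended without day 1 library 1 or 2 or day 2 library 3 (camera adjusted p = 0.957, 0.248 and 0.307). Heat shock proteins and chaperones were higher (median log2 0.17, mean 0.03, camera adjusted p = 0.00239, 0.634 with an estimated correlation). The call ended without day 1 library 3 or day 2 library 2 (0.0648 and 0.0532). In that list a heat shock cognate protein of 70 kDa (PchiChr11G317100) was at 476 ± 25.5 FPKM in CK, 129 ± 20.8 at day 1 and 487 ± 165 at day 2 (log2 of day 2 against day 1 1.92, SE 0.37, edgeR adjusted p = 0.954), and DESeq2 called it (adjusted p = 0.000177). Lipoxygenase 1 (PchiChr2G052390) was at 85.4 ± 121 FPKM at day 1 and 8.45 ± 7.15 at day 2 (edgeR adjusted p = 0.954).

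By edgeR 0 of 22384 genes differed between day 2 and day 1, with a smallest adjusted p of 0.247 and 949 genes at an unadjusted p under 0.05, where chance gives 1119.2. DESeq2 called 72 genes, 44 higher and 28 lower, and limma on log2(FPKM + 1) called 0. In the simulated data of day 1 against CK DESeq2 made 106 false calls and edgeR 2. The 72 genes and the DESeq2 call of PchiChr11G317100 are therefore uncertain. The 4 called lists were 11 without day 2 library 1, 2 without day 2 library 2, 2 without day 2 library 3 and 2 without both treated libraries numbered 2, where the taxane median fell from 2.55 to 0.59.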

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

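The tests of carry-over, of a wrong label, of a few dominant genes and of a shared batch were chosen after the results were seen, while the test of RNA degradation and the counts over other splits were set before theirs.

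In all 4 lists differed between day 2 and day 1 in a direct test at the preset correlation. The median log2 difference was 2.55 for the taxane list, -0.73 for photosynthesis, 0.17 for heat shock proteins and chaperones and -0.42 for WRKY factors, with adjusted p = 0.670, 0.728, 0.634 and 0.670 with an estimated correlation. A CYP94D82 gene (PchiChr3G078150) stood out because all 3 day 1 libraries lay below the CK mean of 0.154 FPKM and all 3 day 2 libraries above it. The log2 difference of day 2 against day 1 was 2.34 at under 1 FPKM, and its test did not pass (edgeR adjusted p = 0.954).

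The number of genes called by edgeR was set against other splits of the same libraries. The real split of day 1 against CK gave 1196 genes and the highest other split 1, and that of day 2 against CK gave 1107 and the highest other 0. With 10 splits of 6 libraries no share can fall under 0.05, so these counts settle nothing about chance. For day 2 against day 1 the real split gave 0 genes (949 at an unadjusted p under 0.05, and 72 by DESeq2) and the highest other split 23, and all 10 splits gave as many as the real one. That split put day 1 library 1 with day 2 libraries 1 and 2. For all 6 treated libraries against CK the real split gave 2121 genes (1468 higher, 653 lower) and the highest other 14. In all 1 of 84 splits gave as many, a share under 0.05 if the libraries are independent. The labels do not state that they are. Day 1 libraries 1 and 3 correlated at 0.958 and 0.959 with the day 2 library of the same number, so chance is not excluded.

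Of the taxane list 13 genes were off in CK libraries 1 and 3 and in day 1 library 2 and on in CK library 2, while others, such as DBAT (PchiChr11G300670) at 35.3 FPKM, were on in day 1 library 2. A wrong label that hides a CK library in day 1 library 2 is argued against by correlations over all tested genes. That library correlated at 0.735 to 0.761 with the CK libraries, which correlated at 0.936 to 0.945 with each other. With the other treated libraries it correlated at 0.795 to 0.839. Over 915 genes higher at day 2 it lay at 1.02 (SE 0.0156) on a scale with CK at 0 and day 2 at 1. The CK libraries lay at -0.18 to 0.11. These genes came from a fit that held day 1 library 2, so their choice may have drawn its position toward 1. Reads carried into CK library 2 from the treated libraries cannot be told apart, although the residuals lay above the 0.2 set for such reads alone. The best mix of libraries chosen by the mean left a median absolute log2 residual of 0.731 (SE 0.0755), more than 2 SE above the bound of 0.5. The mix chosen by the median left 0.661 (SE 0.0857), within 2 SE of that bound. The best single library, day 2 library 1, left a spread of log2 ratios of 0.703 (SE 0.155, 0.1 from counting alone). On the 366 genes of the mix the single libraries left 0.731 to 3.14, and at 0.5 of the share that the taxane genes need 0.0571 (day 1 library 3) to 0.293 (day 2 library 2) of other silent genes lay below the counting limit, against bounds of 0.05 and 0.2. Carry-over on top of expression that CK library 2 had of its own, and a difference between plants in basal taxane expression, which no label allows to be tested, may each remain open beside an effect of MeJA.

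Nuclear photosynthesis genes were lowest in day 1 library 2 and day 2 library 2. A few genes taking most of the counts is argued against by deviations, before scaling, from the other libraries of the same group. The median deviation of the photosynthesis genes lay 2.29 log2 units below that of all tested genes in day 1 library 2. In day 2 library 2 it lay 2.10 below (value of this smaller gap -2.10, SE 0.187). The deviations of both libraries from their group means correlated at -0.0181 (SE 0.0116) over 22384 genes, which are not independent. This cannot argue against a batch shared by both libraries, since shared and opposite deviations may cancel. On the first principal component they lay at 119 and 131, above the other treated libraries (29.7 to 59.0). On the second they lay apart, at 207 and -82.9. A batch effect confined to photosynthesis genes stays open too. RNA degradation that acts by transcript length cannot be told apart by genes matched on length and expression. These fell less, by a difference of -1.14 (SE 0.357) in day 1 library 2 and -1.15 (SE 0.189) in day 2 library 2. Both differences lay within the spread of the bound of -1. Over genes the deviation correlated with length at -0.0494 in day 1 library 2 and 0.0831 in day 2 library 2 (Spearman). The libraries thus shared no trend with length. An effect of MeJA of differing strength between plants may also account for the low photosynthesis genes and was not tested.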

How the results depend on the processing

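Fits with newer edgeR dispersion settings, other edgeR scaling factors, limma on log2(FPKM + 1) and fewer number-2 libraries were chosen after the data were seen. Over all alternatives, 3408 results of named genes stayed on their side of the threshold, 449 lost the call, 126 gained it and 0 that were called in either fit reversed. The sign of the estimate turned in 25 of the 3408, all between day 2 and day 1 and called in neither fit. For lists the 4 numbers were 1809, 61, 100 and 7, with the sign of the median turned in 188 of the 1809, 2 of the 61 and 3 of the 100. Of the 1809, 84 came from the newer dispersion settings, which cannot change the list test. Another 84 came from DESeq2, whose list test reused the edgeR fit with median-of-ratios factors. Neither is a separate check of the lists. Of the counts 130 stayed within 1.5 times and 42 did not. Where a value moved, the cause was not tested.

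Leaving out each library in turn, day 1 against CK gave 134 to 1193 genes, day 2 against CK 48 to 2893, day 2 against day 1 0 to 0 and both days 42 to 1082, and the lists called were 6 to 10, 5 to 11 and 2 to 11. In these fits a group can be left with 2 libraries. Fits of each pair of groups alone gave 534 genes at day 1, 1945 at day 2, 440 in both and 5 lists at day 1. DESeq2 gave 3742, 4012, 72 and 2511. Quantile normalisation gave 2622 genes at day 2, 1417 in both and 2 lists between the days. At day 1 the share of higher calls was 81.3% by edgeR, 64.9% in limma on log2(FPKM + 1) and 49.8% when quantile normalisation was added to that fit. At day 2 these shares were 82.7%, 68.9% and 42.9%. The median log2 of all genes lay at -0.137 and -0.167 after quantile normalisation and at -0.105 at both days in limma on log2(FPKM + 1), against 0.03 at both days by edgeR, so calls of lower genes there are relative to that shift. A mean of at least 5 FPKM left 2 lists between the days, and edgeR with no scaling factors gave 14 lists at day 1. Without both treated libraries numbered 2 there were 1803, 2430 and 1442 genes (day 1, day 2, both) and 2 lists between the days.

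The replicate numbers did not pair the libraries throughout: deviations of same-numbered libraries from their group means correlated at -0.09, -0.12 and -0.10 between CK and day 1, 0.14, 0.13 and 0.00 between CK and day 2, and 0.31, -0.02 and 0.26 between the days, and not every library correlated best with its own number. Between the days libraries 1 and 3 did deviate together, each best with its own number, and library 2 did not. With the replicate number as a block, edgeR called 747 genes at day 1, 865 at day 2, 0 between the days and 592 in both, and 8, 7 and 5 lists.

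The WRKY list between the days had a median log2 of -0.586 to 0.0206 with each library left out and reversed to 0.0206 without day 1 library 2, 0.15 without both treated libraries numbered 2 and 0.16 without these and CK library 2. The photosynthesis list reversed to -0.87 at day 1 with a pseudocount of 0.1, -0.68 with median-of-ratios scaling of FPKM and -1.66 with a mean of at least 5 FPKM, and to -2.08 at day 2 with that mean, in fits that kept 35 genes of the list or, with that mean, 20. Its day 1 median was also negative, with the test's direction unchanged, in limma on log2(FPKM + 1) (-0.81) and after quantile normalisation (-0.83). The fold threshold does not apply to lists.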

Other observations

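All results in this part were looked for after the data were seen.

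KEGG pathways gave a view beyond the fixed lists. Of 118 pathways with at least 10 tested genes, camera called 11 at day 1, 6 at day 2 and 7 between the days at the preset correlation, and 0 in each with an estimated correlation. Plant hormone signal transduction had 41 genes higher and 7 lower of 363 at day 1, and 41 and 9 at day 2 (camera adjusted p = 0.0312 and 0.0139, adjusted p = 0.905 and 0.799 with an estimated correlation). Alpha-linolenic acid metabolism, which holds the steps from linolenic acid to jasmonate, had 9 and 10 genes higher of 84 and none lower by edgeR (median log2 0.81 and 0.94, adjusted p = 0.905 and 0.799 with an estimated correlation). Diterpenoid biosynthesis had a median log2 of 2.31 at day 1 and 2.05 at day 2, with 6 and 7 of 87 genes higher (0.905 and 0.799 as adjusted p with an estimated correlation). Cutin, suberine and wax biosynthesis, of the leaf surface, had 6 of 70 genes lower and 1 higher at day 1 (median log2 -0.50, camera adjusted p = 0.0107, 0.905 with an estimated correlation). Antenna proteins of photosynthesis, which are nuclear-encoded, had median log2 values of -1.40 and -2.11 with 0 of 14 genes called by edgeR. Homologous recombination and base excision repair, pathways of DNA repair, stood lower at day 1, with median log2 values of -0.39 over 107 genes and -0.23 over 56 (camera adjusted p = 0.00851 and 0.0398, 0.905 with an estimated correlation for both).

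Some genes were switched on or off in single libraries. With off as under 0.1 CPM (counts scaled to library size) and on as over 3, 157 genes were off in some libraries and on in all others. 43 of them were on in day 1 library 2 alone, and 31 of these lay on chromosome 7, block 1, between 63266230 and 116789673, 29 of them described as the same germin-like protein, of a family of cell wall proteins active in defence. Their median was 9.97 FPKM in that library (3.94 to 46.9) and 0 in the other 8. None of these 31 genes was tested, since a gene seen in 1 library does not pass the count filter, and no explanation was tested.

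A group of 32 genes was off in exactly CK library 1, CK library 3 and day 1 library 2, and 13 of them belonged to the taxane list. On chromosome 11, block 1, 12 of these genes lay between 22100605 and 59420054, with medians of 3.46 FPKM in CK library 2, 20.5 and 135 in day 1 libraries 1 and 3, and 25.7, 900 and 164 in day 2 libraries 1, 2 and 3. On chromosome 4, block 1000000001, 7 genes described as a putative epoxidase of yew lay between 328765500 and 330676039, and on chromosome 1, block 1, there were 6. A taxadiene synthase (PchiChr11G299420), of the enzyme that makes the taxane skeleton, was at 0, 1.44 and 0 FPKM in CK libraries 1, 2 and 3, at 14.5, 0 and 43.3 at day 1 and at 21.0, 905 and 45.3 at day 2. Of the other 4 genes of that name PchiChr11G299430 and PchiChr11G299440 were also at 0 in day 1 library 2, while PchiChr11G299870 was at 9.42 FPKM and PchiChr11G299880 at 7.56. In the same library DBAT (PchiChr11G300670) was at 35.3 FPKM and the debenzoyltaxol benzoyltransferase PchiChr4G123700 at 96.9, the highest of the 3 day 1 libraries for both. The 2 other genes described like PchiChr4G123700 were at their lowest of day 1 there, PchiChr1G020310 at 17.0 against 85.3 and 159 FPKM and PchiChr4G123650 at 9.09 against 19.7 and 27.1. Of the genes with the 2'-deoxytaxol form of the name, which the table shortens to DBTNBT, PchiChr10G280490, PchiChr10G280500 and PchiChr1G006200 were at 0 and PchiChr1G006190 at 0.175 there, against 7.45 to 209 in day 1 libraries 1 and 3, while PchiChr6G171790 was at 0 in all 3 day 1 libraries.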
